A study of Mus musculus with 6 samples.

How the data were processed

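Liver RNA from male C57BL/6 mice, wild type (WT) or lacking Acss2 (Acss2-KO), was sequenced after a 48-h fast at 22 weeks of age, per the labels, with 3 libraries per genotype. Libraries were made from total RNA with an Illumina TruSeq kit, per the labels' protocols. The labels call the libraries replicates and do not tie each library to an animal, so p-values measure the spread between these libraries, and part of that spread may be technical.

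The deposited table lists 12366 genes with 1 column per library, each gene with an Ensembl identifier, a symbol and a position. Column names matched the sample descriptions. The deposited per-library values are log2 CPM (reads per 1e6 reads), rounded to 2 decimals by the authors, and values below 1 CPM are listed at 0. This was read from the values: 2 to the power of each column sums to between 997061 and 997856 per library, which leaves no room for a scaling factor beyond the library total. The authors also deposited their own log2 fold changes, p-values and adjusted p-values, and the tool behind them is not given in the sources used here. Their log2 fold changes lie 0.15 above the ratio of mean CPM for 9717 genes (SD 0.0063), and their adjusted p-values are Benjamini-Hochberg values over the listed genes. Bowtie 0.12.2 and the build mm8 are named in the submitters' processing notes, with no role given. The coordinates in the deposited table follow another build: gene starts lie a median of 8 bp from those of GRCm38 for 11623 genes. Coordinates are printed as deposited and taken as GRCm38, and the annotation and the counting of multiply matching or antisense reads are not given in the sources used here. Genes with near-identical copies, such as the Mup genes and the globin genes, and genes with an antisense partner are therefore uncertain.

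Sequencing depth was estimated from the steps between the lowest values of each library, since the worth of a read in CPM is the same for each gene of a library. The estimates were 28.8, 30.8 and 23.3 M reads for WT replicates 1 to 3. They were 28.6, 25.7 and 21.8 M reads for Acss2-KO replicates 1 to 3. A value of 5 CPM corresponded to between 109 and 154 reads. Whole reads could not be recovered from values with 2 decimals on a log scale, so no count model was used. The design fixed before the data were examined named a count model for counts and limma for normalized values, and the second branch was followed.

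Deposited values were turned into CPM, with a listed 0 set to 1 CPM, the floor of the table. Genes with a mean of at least 5 CPM over the 6 libraries (9355 genes) were tested on log2(CPM + 1) with limma 3.58.1 in R 4.3.3 (robust empirical Bayes with a mean-variance trend, statmod 1.5.0), without covariates and without a further scaling factor, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Errors are SD for group means in CPM and SE for log2 fold changes. No fold is given for a gene listed at 0 in a whole group.

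A total of 37 gene lists (metabolic pathways, stress and signalling responses, markers of liver zones and of other cell types, signs of RNA handling, and the neighbourhood of Acss2) were written before the data were examined. Of their 656 entries, 584 were found in the table, and 22 genes stood in more than 1 list. The 34 lists with at least 4 tested genes were compared with all other genes by camera (limma) with a preset inter-gene correlation of 0.01. The alternatives were a correlation estimated per list, fry, and lists without shared members. With an estimated correlation the smallest adjusted p over the lists was 0.87.

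The genes named in the text were chosen by a rule fixed before the data were examined: Acss2; the 8 genes with the largest change in each direction among those past the threshold, without overlap between the genotypes, leaving out gene models named Gm or Rik; the 3 genes with the smallest p past the threshold from each list on lipid, acetate and glucose metabolism, and up to 2 from each other list; the 3 most abundant changed genes in each direction; and 10 textbook genes of hepatic lipid handling and fasting. Not every gene that the rule chose is named. Genes named outside this rule are said to have been chosen after their values were seen.

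Alternatives fixed before the data were examined were pseudocounts of 0.5 and 5, median-of-ratios, upper-quartile and quantile scaling, no filter, other thresholds, each library left out in turn, and the replicate number as a block. Chosen after seeing the data were the deposited log2 scale without a pseudocount, trimmed-mean scaling, a minimum of 20 CPM, genes at the floor left out, a variance trend in camera, and leaving out WT replicate 2 and Acss2-KO replicate 1 together. The procedure was tested on simulated libraries with the depths and levels of this comparison: of 50 genes changed at each size among 9490 genes, 12 were recovered at 1.5-fold, 44 at 2-fold and 50 at 3-fold, with 5 other genes called, and no gene was called when none was changed. The simulation gave every gene the same residual SD (0.25 log2) and independent errors, with 200 genes changed in all. Its rates therefore do not describe genes with a wider spread, correlated genes or libraries that differ as a whole.

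Mitochondrial protein genes were aligned to chromosome 1 of NCBIM37 with blastn 2.17.0 (megablast, at least 95% identity), and the 36-base words of zinc finger gene transcripts were compared with all coding transcripts of the same annotation. Coordinates of both builds were kept apart.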

Results

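Liver transcriptomes of 48-h fasted male mice were compared between 3 WT libraries and 3 Acss2-KO libraries. Acss2 encodes the cytosolic and nuclear enzyme that makes acetyl-CoA from acetate. Estimated depth ranged from 21.8 to 30.8 M reads per library. The WT libraries correlated with each other at Pearson r between 0.948 and 0.963 across genes, the Acss2-KO libraries at 0.918 to 0.968, and pairs from different genotypes at 0.787 to 0.923 (genes are not independent replicates). No pair of libraries held the same values. The leading principal component held 71.5% of the variance and separated the genotypes, with WT scores between -45.6 and -38.0 and Acss2-KO scores of 62.4, 16.9 and 44.0 for replicates 1, 2 and 3.

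Acss2 (ENSMUSG00000027605, chromosome 2, 155517948 to 155585724) was measured at 74.0, 81.0 and 73.5 CPM in the WT libraries and at 1.37, 3.56 and 2.35 CPM in the Acss2-KO libraries. The means were 76.2 ± 4.19 CPM (SD, n = 3) and 2.42 ± 1.10 CPM (SD, n = 3). This is a 23.3-fold lower level (log2 fold change -4.54, SE 0.24, limma adjusted p = 2.6e-05), and the library labels and the level of the targeted gene match in each of the 6 libraries.

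The comparison asks which liver transcripts differ when Acss2 is missing during a fast. Lepr, the leptin receptor (chromosome 4, 101717404 to 101815352), rose from 10.4 ± 6.46 to 664 ± 378 CPM (55.6-fold, log2 fold change 5.80, SE 0.70, adjusted p = 0.0032). Pdk4, a kinase that inhibits pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), rose 29.2-fold, and Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29090979 to 29100722), rose 29.0-fold, from 7.64 ± 2.49 to 250 ± 72.6 CPM. Log2 fold changes were 4.53 for the cytochrome P450 gene Cyp2b10, 4.47 for the metallothionein gene Mt2, 4.30 for Eif4ebp3, 4.01 for the ferritin receptor gene Scara5 and 3.81 for Ddit4, an inhibitor of mTORC1 signalling, with adjusted p-values between 2.6e-05 and 0.043. Mup19, a major urinary protein gene whose reads can be shared with other Mup genes (chromosome 4, 61778324 to 61782269), was measured at 217, 292 and 274 CPM in WT and listed at 0 in the 3 Acss2-KO libraries. Car3, a carbonic anhydrase (chromosome 3, 14863512 to 14872523), fell from 759 ± 288 to 6.67 ± 3.15 CPM (101-fold lower, adjusted p = 0.00017). Rgn, the calcium-binding protein regucalcin (chromosome X, 20549787 to 20562089), fell from 501 ± 41.0 to 12.6 ± 11.3 CPM. Log2 fold changes were -5.36 for the corticosteroid-binding globulin gene Serpina6, -5.20 for the methyltransferase gene Inmt, -4.47 for Cyp1a2 and -4.36 for the thyroxine-binding globulin gene Serpina7. Some rises differed in size among Acss2-KO replicates 1, 2 and 3. Lepr was at 929, 231 and 832 CPM, Pdk4 at 1580, 393 and 1650 CPM, and Ddit4 at 347, 23.6 and 107 CPM. The Ddit4 call was lost without WT replicate 1 (adjusted p = 0.14), WT replicate 2 (0.15) or Acss2-KO replicate 3 (0.13), with a pseudocount of 5 (0.062) and with the replicate number as a block (0.093). With WT replicate 2 and Acss2-KO replicate 1 both left out, adjusted p was 0.064 for Lepr, 0.13 for Pdk4, 0.16 for Cyp2b10, 0.11 for Serpina6 and 0.25 for Ddit4.

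**Figure D1:**
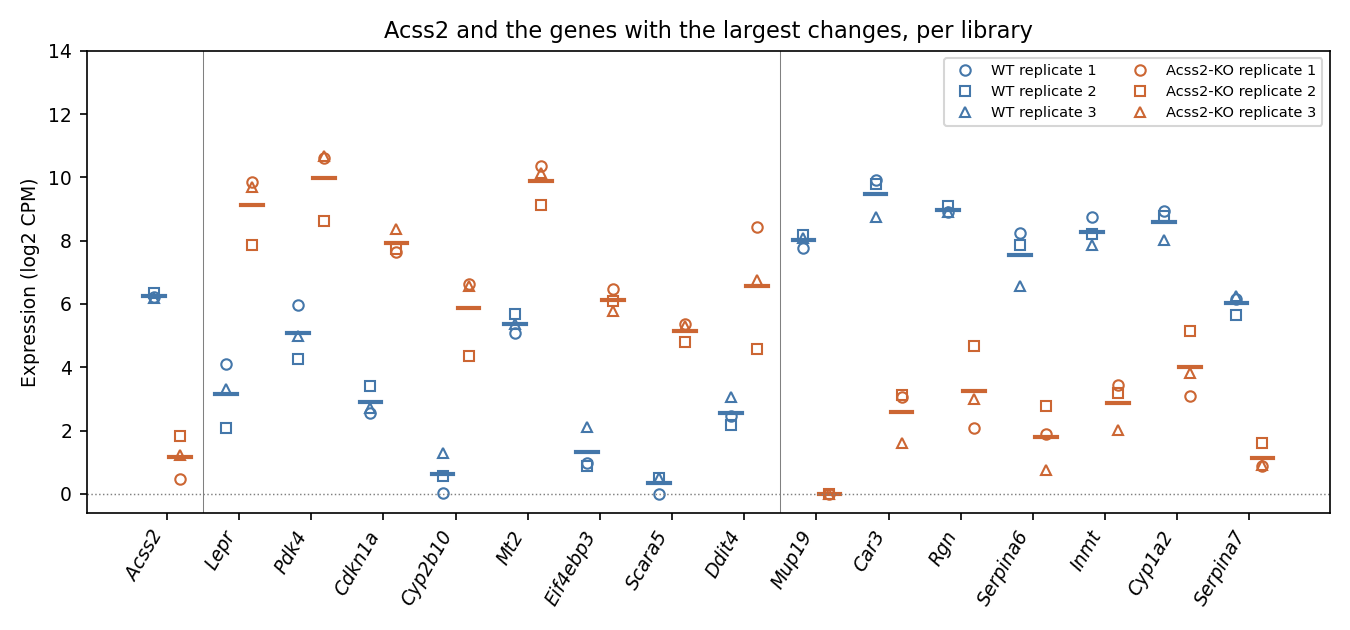
Expression of Acss2 (left), the 8 genes with the largest rise (middle) and 7 of the genes with the largest fall (right), in log2 CPM. The risers and fallers were picked among changed genes without overlap between the genotypes, so the gap between the genotypes follows from that choice. Each point is a library, bars are means of 3 libraries, and the dotted line at 0 is the floor of the table. Mup19 is listed at 0 in all 3 Acss2-KO libraries.

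Of the 9355 genes tested, 3413 changed between the genotypes, 1252 higher and 2161 lower in Acss2-KO. At an absolute log2 fold change of 1 or more, 491 were higher and 1034 lower. The groups did not overlap for 4947 of the tested genes (52.9%, against 10% by chance), among them 3372 of the changed genes. The most abundant genes that rose were Mat1a, which makes S-adenosylmethionine (6990 ± 343 to 17900 ± 811 CPM), the omega-hydroxylase gene Cyp4a14 (7680 ± 573 to 13400 ± 932 CPM) and the urea cycle gene Cps1 (2510 ± 390 to 11700 ± 1250 CPM). The most abundant genes that fell were Apoe (17800 ± 3340 to 9730 ± 1540 CPM), Cyp2e1 (13300 ± 2350 to 6470 ± 1970 CPM) and Apoa2 (7700 ± 1180 to 4630 ± 512 CPM). The split between higher and lower depended on scaling. The median log2 fold change of all tested genes was -0.12 on CPM. With the libraries scaled to remove that shift, 1690 genes were higher and 1765 lower (median of ratios), 1622 and 1815 (upper quartile), 1710 and 1729 (trimmed mean) or 1816 and 1641 (quantile). The total of 3413 was 2148 without WT replicate 1, 2125 without WT replicate 2 and 1758 without Acss2-KO replicate 3. Higher calls numbered 780 without WT replicate 2, 801 without Acss2-KO replicate 1 and 519 without Acss2-KO replicate 3. Lower calls numbered 1302 without WT replicate 1, 1345 without WT replicate 2 and 1239 without Acss2-KO replicate 3. With both doubted libraries left out, 715 were higher and 1319 lower. Of these abundant genes, Apoe lost its call without WT replicate 1 (adjusted p = 0.072), WT replicate 2 (0.089), Acss2-KO replicate 1 (0.059) or Acss2-KO replicate 3 (0.087). Apoa2 lost its call without the same libraries (0.070, 0.061, 0.060 and 0.12). Apoa2 also lost it with median-of-ratios (0.060), upper-quartile (0.063) and trimmed-mean scaling (0.062). Cyp4a14 lost it without WT replicate 2 (0.076) or Acss2-KO replicate 3 (0.052) and with quantile scaling (0.055). Cyp2e1 lost it without WT replicate 1 (0.055), WT replicate 2 (0.057) or Acss2-KO replicate 3 (0.068). By the adjusted p-values the authors deposited, 1541 genes have a positive and 1818 a negative log2 fold change past 0.05. Of the 2133 such genes among those tested here, 91.2% changed here with the same sign. These 1945 genes are 57% of the 3413 that changed here.

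Genes of cholesterol synthesis fell together. Of 24 measured SREBP-2 targets and pathway genes, 18 fell and 1 rose (21 and 1 adjusted over the list alone), with a median log2 fold change of -1.47 (camera adjusted p = 6.03e-05, and adjusted p = 0.87 with an estimated correlation). Stard4, a sterol carrier, fell from 82.6 ± 19 to 9.74 ± 3.40 CPM (log2 fold change -2.98, SE 0.25), and Sc5d from 257 ± 28.6 to 58.9 ± 17.8 CPM. For every list in the sections that follow, the count adjusted over the list alone was the same unless it is given.

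Genes of acetate and acetyl-CoA metabolism other than Acss2 did not shift as a list (camera adjusted p = 0.59), with 5 of 12 lower and 1 higher. Acat2 (log2 fold change -1.63, SE 0.28), the mitochondrial citrate carrier gene Slc25a1 (-0.61, SE 0.16) and Acly, which makes acetyl-CoA from citrate (-0.66, SE 0.18), were lower. Among 20 genes of fatty acid and triglyceride synthesis, 9 were lower and 3 higher (12 and 4 adjusted over the list alone), and the list did not pass the test (adjusted p = 0.17). The elongase gene Elovl6 (-1.64, SE 0.17), Acsl3 (-1.55, SE 0.23) and the desaturase gene Fads2 (-1.36, SE 0.22) were lower. Fasn, the fatty acid synthase, went from 128 ± 26.9 to 222 ± 59.2 CPM (0.78, SE 0.24, adjusted p = 0.034). The Fasn call was lost without WT replicate 1 (adjusted p = 0.10), WT replicate 3 (0.097), Acss2-KO replicate 1 (0.091) or Acss2-KO replicate 3 (0.076). Acly lost its call without WT replicate 1 (0.079), WT replicate 2 (0.080) or Acss2-KO replicate 3 (0.088), and Slc25a1 without the same libraries (0.073, 0.069 and 0.093) and with quantile scaling (0.051).

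Genes of fatty acid uptake and lipid droplets moved in both directions, 9 of 27 higher and 8 lower (9 and 9 adjusted over the list alone), with no shift of the list (camera adjusted p = 0.59). The droplet protein genes Cidec (74.6 ± 4.58 to 462 ± 83.8 CPM, log2 fold change 2.60, SE 0.19) and Plin5 (85.0 ± 15.9 to 297 ± 50.7 CPM) were higher. The fatty acid transporter gene Cd36 fell from 250 ± 44.9 to 44.0 ± 4.61 CPM (-2.47, SE 0.19, adjusted p = 0.00017). Fabp1, the liver fatty acid binding protein, fell from 4880 ± 1200 to 825 ± 381 CPM (-2.63, SE 0.33), and Pparg, a lipogenic nuclear receptor, from 16.2 ± 2.69 to 6.93 ± 1.15 CPM. The lipase inhibitor gene Angptl4 rose from 183 ± 37.9 to 461 ± 155 CPM. Lpl, the lipoprotein lipase, did not pass the test (14.4 ± 9.50 and 12.5 ± 14.7 CPM, adjusted p = 0.64). In lipoprotein assembly 5 of 17 genes were lower and 1 higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.57), with Lipc (-2.18, SE 0.23) and Apoc1 (-1.39, SE 0.25) lower and Apoa4 (1.34, SE 0.22) higher.

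The fasting programme of fatty acid oxidation and ketone bodies did not shift as a whole. Of 31 PPARα targets and oxidation genes 5 were higher and 7 lower (camera adjusted p = 0.98), with Cyp4a31 (log2 fold change 2.13, SE 0.28) and Pdk4 (4.87, SE 0.69) higher and the pantetheinase gene Vnn1 (-1.85, SE 0.29) lower. Of 6 ketone body genes 2 were higher and 3 lower (adjusted p = 0.98, direction up by the test, although the median was -0.58). The monocarboxylate transporter genes Slc16a6 (2.48, SE 0.24) and Slc16a1 (1.12, SE 0.19) rose. Bdh1, the β-hydroxybutyrate dehydrogenase, fell from 570 ± 121 to 70.5 ± 75.2 CPM. Cpt1a, the carnitine palmitoyltransferase (1120 ± 322 and 1210 ± 64.3 CPM), and the gluconeogenic gene Pck1 (4330 ± 846 and 4210 ± 1220 CPM) did not pass the test, with adjusted p-values of 0.67 and 0.88. Fgf21, a fasting hormone, was at 38.8 ± 5.54 and 16.8 ± 10.1 CPM (adjusted p = 0.070), and passed without Acss2-KO replicate 1 (0.026) or Acss2-KO replicate 2 (0.027). The sign of the Cpt1a value turned without WT replicate 3 (-0.12), and that of Pck1 without WT replicate 1 (0.08), Acss2-KO replicate 2 (0.10) or Acss2-KO replicate 3 (0.01). Bdh1 lost its call without WT replicate 1 (adjusted p = 0.088), WT replicate 2 (0.096) or Acss2-KO replicate 3 (0.068).

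Genes of amino acid breakdown and the urea cycle were higher as a list, with 10 of 22 higher and 5 lower (12 and 5 adjusted over the list alone, median log2 fold change 0.61, camera adjusted p = 0.012, and adjusted p = 0.87 with an estimated correlation). Cps1 (2.23, SE 0.21) and the lysine-degrading enzyme gene Aass (2.33, SE 0.25) rose; the urea cycle gene Otc, chosen after its value was seen, went the other way (-1.91, SE 0.49). Gluconeogenesis and fasting genes shifted upward, 7 of 19 higher and 2 lower (camera adjusted p = 0.0195, and 0.87 as the adjusted p with an estimated correlation). Slc37a4, the glucose-6-phosphate transporter (1.48, SE 0.22), and the aspartate aminotransferase gene Got1 (2.98, SE 0.44) rose, and the glycerol channel gene Aqp9 fell (-1.13, SE 0.23). Genes of the committed steps did not pass the test: besides Pck1, log2 fold changes were -0.12 for G6pc, -0.13 for Fbp1 and -0.03 for Pcx (adjusted p between 0.63 and 0.95), which were chosen after their values were seen. Both list calls were lost with quantile scaling (adjusted p = 0.059 each) and on leaving out genes shared with another list (0.14 for amino acid breakdown, 0.11 for gluconeogenesis). The gluconeogenesis call was also lost without WT replicate 2 (0.05 after rounding) or WT replicate 3 (0.068) and with both doubted libraries left out (0.067). In glycolysis 7 of 14 genes were lower and 2 higher (camera adjusted p = 0.74), with Slc2a2, the hepatic glucose transporter (-2.16, SE 0.44), and Pklr (-1.35, SE 0.25) lower and Gapdh (0.93, SE 0.16) higher.

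Pericentral hepatocyte markers were lower and periportal markers higher as lists. Of 9 pericentral markers 8 fell (median log2 fold change -1.43, camera adjusted p = 0.0017, and adjusted p = 0.87 with an estimated correlation), among them Cyp1a2 (397 ± 122 to 19.3 ± 14.3 CPM) and the ornithine aminotransferase gene Oat (2760 ± 417 to 918 ± 276 CPM). Of 11 periportal markers 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.70, camera adjusted p = 0.0043, and adjusted p = 0.87 with an estimated correlation), among them Cdh1 (12.1 ± 3.92 to 61.3 ± 12.4 CPM) and Arg1 (1080 ± 420 to 3320 ± 547 CPM). The periportal marker that fell was Cyp2f2 (589 ± 213 to 229 ± 150 CPM), chosen after its value was seen. Both lists share genes with other lists, and without the shared genes adjusted p was 0.060 for pericentral and 0.43 for periportal markers. Bile acid genes were at the edge of the threshold, 10 of 17 lower and 1 higher (camera adjusted p = 0.0501). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 62.3 ± 25.0 to 2 ± 0.704 CPM and the transporter gene Slco1a1 from 186 ± 71.5 to 17.5 ± 2.96 CPM. Of 17 drug-metabolising P450 genes 9 were lower and 3 higher (11 and 3 adjusted over the list alone, camera adjusted p = 0.10), with Cyp2c37 (-1.29, SE 0.20) lower and Cyp2b10 higher. Male-biased genes did not shift (3 higher and 4 lower of 12, adjusted p = 0.67, Slco1a1 and Nudt7 lower), nor did female-biased genes (4 higher and 3 lower of 7, adjusted p = 0.65, direction up although the mean was -0.23). Of the latter, Fmo2 rose (1.81, SE 0.24) and Cyp2b9 was listed at 0 in the 3 Acss2-KO libraries against 41.1, 31.8 and 11.5 CPM in WT.

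**Figure D2:**
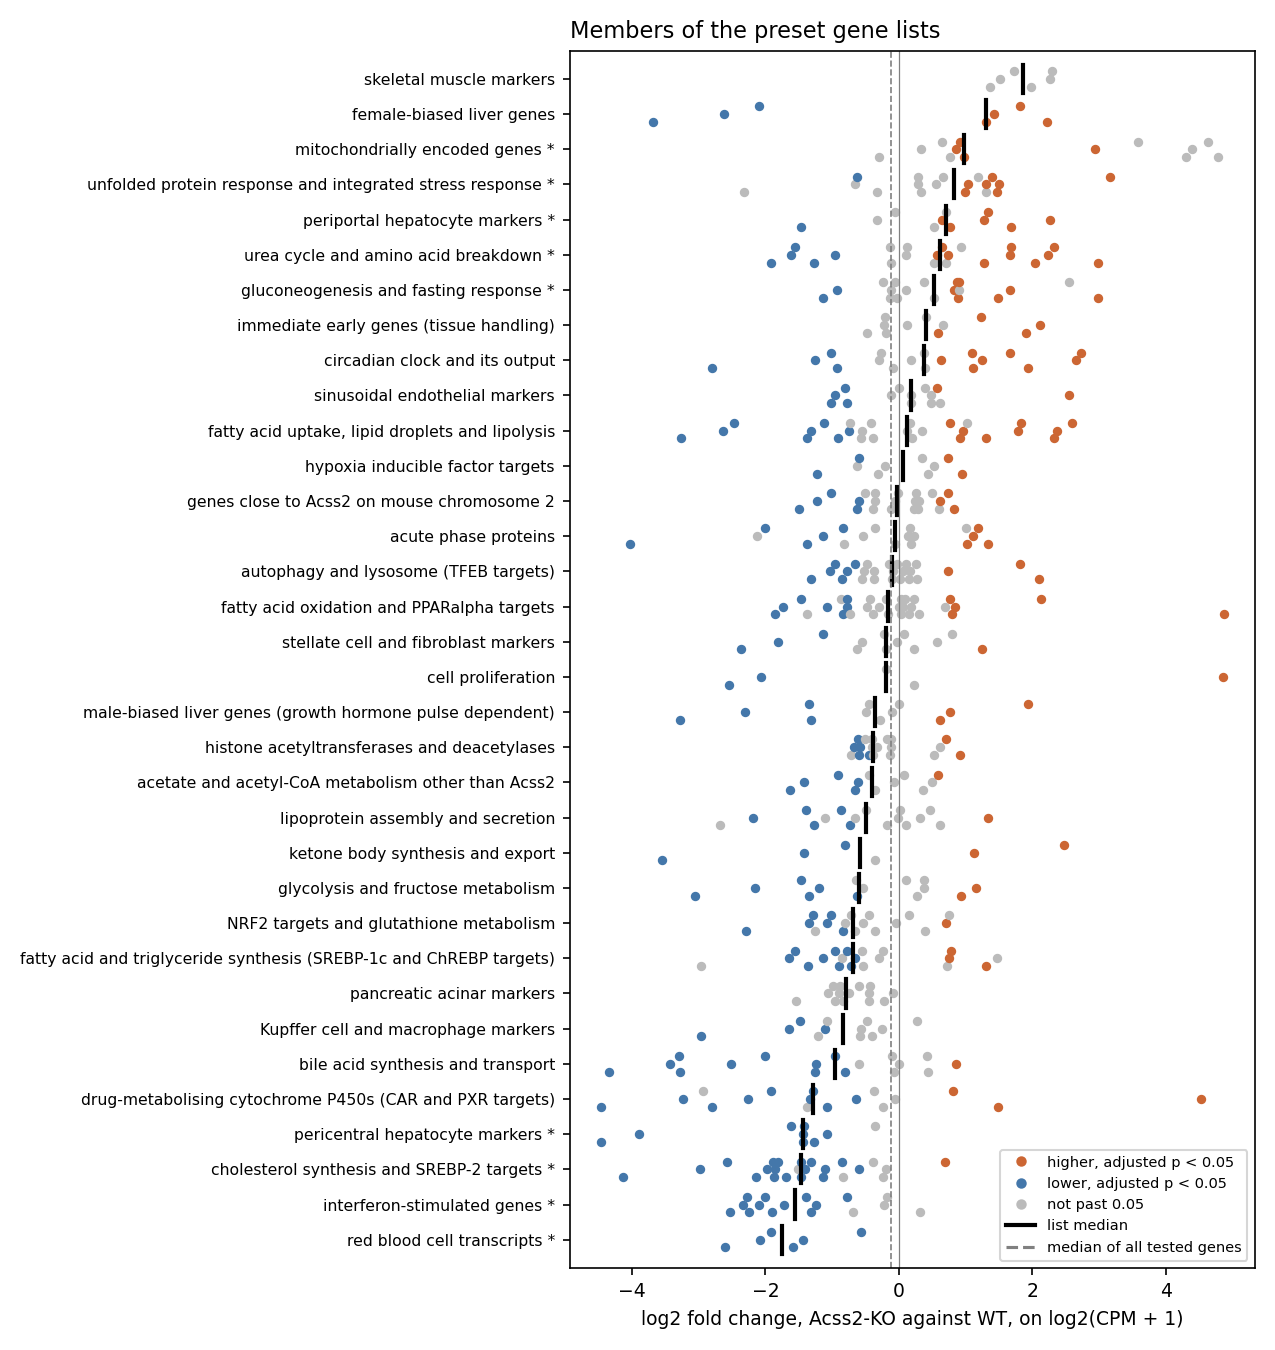
Members of the 34 tested gene lists, sorted by list median: the x axis is the log2 fold change of Acss2-KO against WT on log2(CPM + 1), points are genes (orange higher and blue lower with adjusted p under 0.05, grey not), black bars are list medians, the dashed line is the median of all tested genes (-0.12), and a star marks camera adjusted p under 0.05 with the preset correlation. Red blood cell transcripts, interferon-stimulated genes and cholesterol synthesis genes have the lowest medians among the starred lists (-1.75, -1.55 and -1.47).

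Unfolded protein and integrated stress response genes were higher, 8 of 18 against 1 lower (8 and 3 adjusted over the list alone, median log2 fold change 0.82, camera adjusted p = 0.0043, and adjusted p = 0.87 with an estimated correlation). Asns, the asparagine synthetase, rose from 2.16 ± 1.12 to 26.5 ± 6.06 CPM and the chaperone gene Hsp90b1 from 570 ± 38.9 to 1530 ± 382 CPM. Members that went the other way, chosen after their values were seen, included Trib3 (-0.62, limma adjusted p = 0.029). Ddit3 (-0.65, 0.054) and Gdf15 (-2.32, 0.056) were also below WT and did not pass. Interferon-stimulated genes were lower, 12 of 16 with none higher (13 adjusted over the list alone, median -1.55, camera adjusted p = 0.000835, and adjusted p = 0.87 with an estimated correlation), with Irf9 (-2.09, SE 0.29) and Rtp4 (-1.72, SE 0.25) as examples. Beside them, 4 of 12 Kupffer cell and macrophage markers were lower and none higher (camera adjusted p = 0.105), and the leukocyte gene Ptprc was lower (-1.40, SE 0.31). Of 18 clock genes 8 were higher and 4 lower (camera adjusted p = 0.0501). Ciart (11.5 ± 3.64 to 79.8 ± 8.54 CPM) and Per1 (45.7 ± 7.71 to 303 ± 116 CPM) rose. Dbp, chosen after its value was seen, fell (87.5 ± 15.2 to 13.1 ± 8.43 CPM). The collection times are not given in the labels used here.

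Other preset lists did not pass the test. In NRF2 and glutathione genes 6 of 18 were lower and 1 higher (camera adjusted p = 0.17), with Gsta4 (log2 fold change -2.29) and Gpx1 (-1.35) lower. Autophagy and lysosome genes counted 3 higher and 6 lower of 25 (0.85), with Wipi1 at 2.10 and Gabarapl1 at -1.31. Hypoxia targets counted 2 higher and 2 lower of 10 (2 and 3 adjusted over the list alone, 0.85), with Egln3 at -1.22 and Bnip3 at 0.94. Histone acetyltransferases and deacetylases counted 2 higher and 5 lower of 19 (0.57), with Sirt3 at -0.58 and Hdac3 at -0.61. Acute phase genes counted 4 higher and 5 lower of 19 (0.98, direction up although the mean was -0.36), with Saa4 at -4.03 and Itih3 at 1.11. The proliferation list counted 1 higher and 2 lower of 5 (0.98, direction down although the mean was 0.05). Its 1 higher member was the cell cycle inhibitor Cdkn1a (4.86). Tk1 (-2.06) and Ccnd1 (-2.55, chosen after its value was seen) were lower. Since the list mixes an inhibitor with genes of proliferation, its mean and test do not show whether the latter shifted. Immediate early genes, a sign of tissue handling, counted 4 higher and none lower of 11 (adjusted p = 0.093), with Btg2 at 1.23 and Klf4 at 1.91. Bnip3 lost its call without WT replicate 1 (adjusted p = 0.068), WT replicate 2 (0.069) or Acss2-KO replicate 3 (0.061). Sirt3 lost it without WT replicate 1 (0.075) or Acss2-KO replicate 3 (0.084). Hdac3 lost it without WT replicate 1 (0.074), WT replicate 2 (0.076), Acss2-KO replicate 1 (0.073) or Acss2-KO replicate 3 (0.091). Klf4 lost it without WT replicate 1 (0.067), WT replicate 2 (0.067), WT replicate 3 (0.065) or Acss2-KO replicate 3 (0.058).

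Mitochondrially encoded genes were higher, with 4 of 13 past the threshold, none lower and a median log2 fold change of 0.97 (camera adjusted p = 0.000835, and adjusted p = 0.87 with an estimated correlation). The complex I subunit genes mt-Nd6 (1100 ± 247 to 2040 ± 93.1 CPM) and mt-Nd5 (3620 ± 792 to 6480 ± 296 CPM) rose. For mt-Nd6 the call was lost without WT replicate 1 (adjusted p = 0.058), WT replicate 2 (0.055) or Acss2-KO replicate 3 (0.059), and for mt-Nd5 without the same libraries (0.075, 0.062 and 0.063). The WT libraries differed from each other in 6 neighbouring genes from mt-Co2 (start 7013) to mt-Nd4l (end 10173), chosen after their values were seen: mt-Co3 was listed at 9.11, 3.54 and 11.94 log2 CPM in WT replicates 1, 2 and 3 and at 12.75, 12.57 and 12.60 in the Acss2-KO libraries. These 6 genes have a copy on chromosome 1 that covers at least 99.1% of each with full identity. The copy also covers 63.6% of mt-Nd4 and 31.3% of mt-Co1. The median range of the 6 genes among the WT libraries was at least 8.13, since mt-Atp8, mt-Nd3 and mt-Nd4l are listed at 0 in WT replicate 2, against 0.64 for the other 7 genes. Those 7 genes alone counted 3 higher and none lower (median 0.76, camera p = 0.0059, and p = 0.30 with an estimated correlation). The 3 were mt-Nd5, mt-Nd6 and the partly covered mt-Nd4, and the median is the value of the partly covered mt-Co1. This set is therefore not free of the copy, and the 5 genes with no part covered were not tested as a set.

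**Figure D3:**
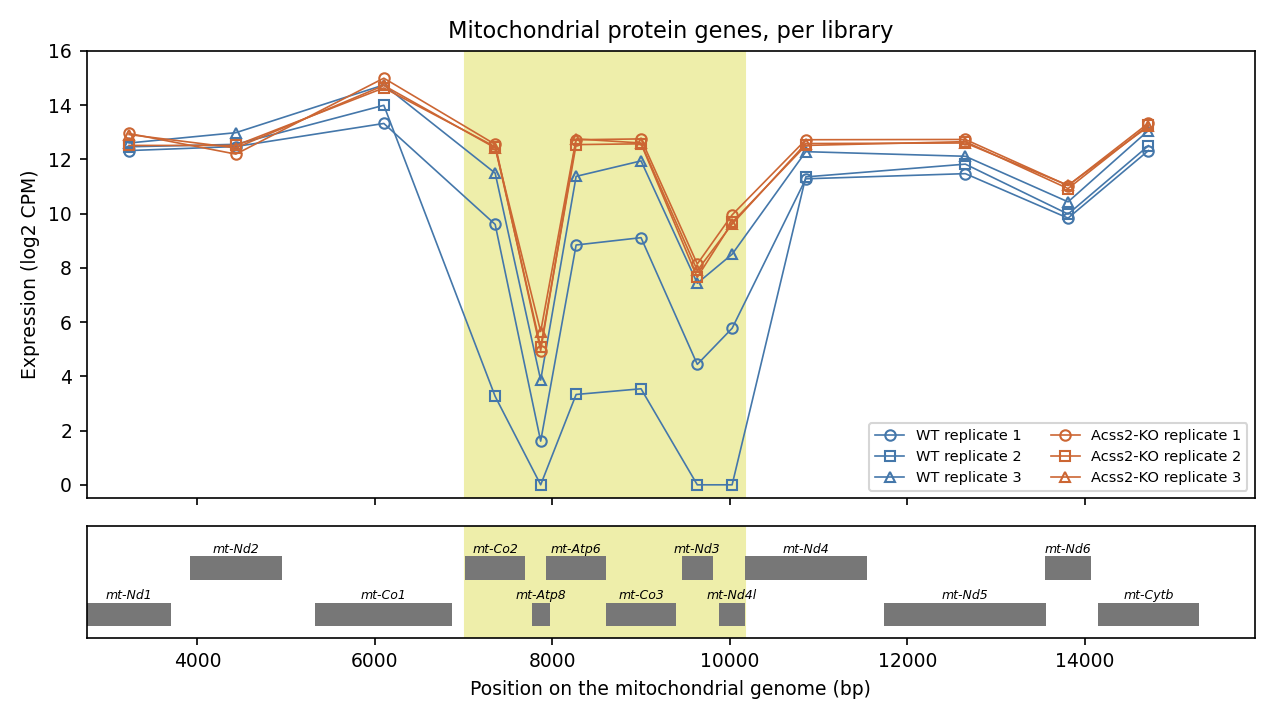
Expression of the 13 mitochondrial protein genes in log2 CPM (upper panel) against their position in bp on the mitochondrial genome (lower panel, grey bars), 1 line per library, blue for WT and orange for Acss2-KO. The shaded stretch from 7013 to 10173 holds the genes that a copy on chromosome 1 covers by at least 99.1%. There the WT libraries lie apart (mt-Co3 at 9.11, 3.54 and 11.94), while the Acss2-KO libraries lie together. Outside it the median range among WT libraries is 0.64. The copy reaches past both edges, into mt-Co1 and mt-Nd4, whose WT ranges are 1.42 and 1.

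Of the lists of other cell types, that of red blood cell transcripts passed the test. Red blood cell transcripts fell in 6 of 6 genes (median log2 fold change -1.75, camera adjusted p = 0.0025, and adjusted p = 0.87 with an estimated correlation), such as Alas2 (50.4 ± 8.96 to 7.69 ± 2.81 CPM) and the globin gene Hbb-bt (18.4 ± 7.05 to 3.39 ± 0.793 CPM). Kupffer cell and macrophage markers counted 4 lower and none higher of 12 (camera adjusted p = 0.105), among them Lyz2 (-1.65, SE 0.40) and Cd5l (-2.96, SE 0.74). Stellate cell and fibroblast markers counted 1 higher and 3 lower of 13 (0.79), with Lrat at -1.81 and Col3a1 at -2.37, and sinusoidal endothelial markers 2 higher and 4 lower of 14 (0.59), with Lyve1 at 2.55 and Clec4g at -1.01. The lists of cholangiocyte, adipocyte and lymphocyte and neutrophil markers had too few measured genes to test. Of the cholangiocyte markers Spp1 fell (-2.08) and Sox9 rose (1.33), of the adipocyte markers Car3 fell and Fabp4 rose (1.83), and of the lymphocyte and neutrophil markers Ptprc fell (-1.40). Lyz2 lost its call without WT replicate 2 (adjusted p = 0.054) or WT replicate 3 (0.063). Cd5l lost it without WT replicate 1 (0.057), WT replicate 2 (0.088) or Acss2-KO replicate 3 (0.079). Fabp4 lost it without WT replicate 1 (0.058) or WT replicate 2 (0.062). Pancreatic acinar markers varied among libraries of both genotypes and counted none higher or lower of 14 (camera adjusted p = 0.98, direction up although the median was -0.79). Their summed level was 41.6, 8060 and 477 CPM in WT replicates 1, 2 and 3 and 1830, 21.5 and 774 CPM in the Acss2-KO replicates. Skeletal muscle markers summed to 537 CPM in Acss2-KO replicate 1 and to at most 14.1 CPM in any other library, and none of the 6 tested passed (camera adjusted p = 0.105).

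Genes close to Acss2 on chromosome 2 did not shift as a list (3 higher and 5 lower of 22, 4 and 5 adjusted over the list alone, camera adjusted p = 0.95, direction up although the mean was -0.10). Uqcc1 (38.1 ± 1.20 to 15.7 ± 1.73 CPM, log2 fold change -1.23, SE 0.16) and the centrosomal gene Cep250 (15.3 ± 3.88 to 4.67 ± 0.0373 CPM, -1.50, SE 0.20) were lower. Over all lists, 9 of 34 passed camera with the preset correlation and none with an estimated correlation, where 1 list had an unadjusted p under 0.05. By fry, which asks whether the genes of a list move on balance in either direction without comparing them with other genes, 9 lists passed, 7 of them the same. The gluconeogenesis list (adjusted p = 0.15) and the mitochondrial list (0.11) did not pass by fry, while lipogenesis (lower, 0.036) and bile acid genes (lower, 0.048) did. Without Acss2-KO replicate 2, 15 lists passed camera.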

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

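The tests of the mitochondrial genes and of the muscle and squamous genes were chosen only after the result was seen, and the count over other splits was planned. The genes named here were chosen after their values were seen.

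Among the genes left out of the test by the minimum of 5 CPM, 1 gene was at the floor in the 3 WT libraries and at 4 CPM or more in the 3 Acss2-KO libraries. It was Tg, the thyroglobulin gene, at 6.15, 7.73 and 4.89 CPM in the Acss2-KO libraries. No explanation was tested.

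The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3413 changed genes and the highest of the other splits 0 (1 of the 10 splits gave as many, the real one included). Every other split mixes the genotypes in both groups, so a genotype difference widens the spread within groups and lowers the count. The 0 therefore does not show what chance alone would give. For the preset lists the real split gave 9 and the highest other split 11 (5 of the 10 gave as many, the real one included). The other splits hold unequal numbers of each genotype in their groups and so keep part of any genotype difference. These list counts therefore do not show what chance alone would give either.

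The mitochondrial genes from mt-Co2 to mt-Nd4l lay far apart among the WT libraries, mt-Nd4l by at least 8.5 log2 units, since it is listed at 0 in WT replicate 2. The median range of the 6 genes covered over more than 90% of their length by a chromosome 1 copy (24619243 to 24622404 in NCBIM37) was at least 7.5 log2 units above that of the other 7, of which mt-Nd4 (63.6%) and mt-Co1 (31.3%) are covered in part, as sharing of reads with that copy predicts. A lower mitochondrial content in WT replicate 2 is argued against by those 7 genes, whose median there was -0.15 log2 units relative to the other WT libraries, the same as for the 5 genes with no part covered. Covered genes and copies summed to nearly the same in WT replicates 2 and 1 (1890 and 1960 CPM, -0.05 log2 units), as a transfer of reads without loss predicts for that pair, but such a transfer is argued against for WT replicate 2 relative to WT replicate 3 (-2.42) and to the Acss2-KO libraries (-3.39). What stays open is why the sum differs between those libraries, for example whether reads that match both places were dropped to different extents, and no biological explanation was tested for a difference within WT.

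Muscle and squamous epithelium genes were high in Acss2-KO replicate 1: Acta1 at 199 CPM, Myh1 at 115, Krt4 at 63.1 and Krt13 at 62.2, against at most 3.63 CPM in any other library. Of the 9 preset muscle genes in the table, 8 were over 4-fold higher there than in each other library, as tissue other than liver in that library predicts, and none of these genes is among the calls. Of 1252 genes called higher, 768 were called again without Acss2-KO replicate 1, 1194 without replicate 2 and 519 without replicate 3. The lowest count, predicted for replicate 1 if the higher calls rested most on it, was thus not seen there. These counts also depend on how alike the remaining Acss2-KO libraries are. Pearson r between those was 0.963 without replicate 1, 0.968 without replicate 2 and 0.918 without replicate 3. The counts therefore cannot decide how far the higher calls rest on Acss2-KO replicate 1. In the authors' deposited table, 72 genes with an adjusted p under 0.05 are at 4 CPM or more in that library and at 2 CPM or less in the other 5, Krt13 among them (2e-41). Which tissue it was, and whether it entered at dissection or in the sequencing run, stays open.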

How the results depend on the processing

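Direction and call of Acss2 held under each alternative (log2 fold change between -5.08 and -3.46). Without each library in turn, changed genes ranged from 1758 to 4028 (higher 519 to 1608, lower 1239 to 2420) and shifted lists from 8 to 15, with both highest counts, 4028 and 15, without Acss2-KO replicate 2, the Acss2-KO library nearest to WT on the leading component; the cause was not tested. Fewer genes were also called at a minimum of 20 CPM (1853; 741 higher, 1112 lower; fewer genes tested), with 2 doubted libraries left out (2034; 715 and 1319), at an adjusted p of 0.01 (1496; 505 and 991) and at an absolute log2 fold change of 1 or more (1525; 491 and 1034), the last 2 by construction. The minimum of 20 CPM and the doubted libraries were chosen after seeing the data. Both pseudocounts and the deposited scale called between 3388 and 3440 genes, at least 3387 of them shared with the 3413, and the 4 scalings 3437 to 3457, with 2882 to 3064 shared. Shifted lists numbered 14 without a filter, 5 with members of 1 list only (smaller lists) and 0 with an estimated correlation, the cause of the first not tested. The sign of Pck1 reversed with median-of-ratios and trimmed-mean (0.06 each) and upper-quartile scaling (0.03), which remove the overall shift, and ranged from -0.28 to 0.10 over left-out libraries; Cpt1a ranged from -0.12 to 0.30. Neither passed the test, and the cause was not tested. Of the 96 called genes that the rule chose besides Acss2, 18 lost the call on leaving out at least 1 library (adjusted p 0.052 to 0.15) and none reversed; with the 2 doubted libraries left out, 21 lost it. Same-numbered libraries did not deviate together (correlations -0.10, -0.14 and 0.09), which gives no sign that the numbers pair the samples. With 3 libraries per genotype this check cannot exclude a pairing. With the replicate number as a block 3397 genes were called, 3165 of them shared, and 15 lists. Under that block Ddit4 lost its call and Fgf21 gained it. The planned count-model tests were not run because the values are not counts. At 5 CPM a value rests on 109 to 154 reads, and below 1 CPM the table holds no information.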

Other observations

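Symbol families, 10-Mb bins and on-off genes, and the genes named as examples here, were chosen after their values were seen, and the tests of the zinc finger bins and the glucocorticoid genes were fixed before their results were seen.

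Among 103 families of genes with the same symbol stem and at least 10 tested members, 8 passed camera with the preset correlation (Benjamini-Hochberg over the families) and none with an estimated correlation (adjusted p = 1 each). Aldo-keto reductase genes (Akr) fell in 10 of 10 members (median log2 fold change -2.03), UDP-glucuronosyltransferases (Ugt) in 8 of 13 (-1.43) and carboxylesterases (Ces) in 6 of 12 (-2.16), with none higher. Mitochondrial ribosomal proteins of the large subunit (Mrpl) fell in 16 of 47 (-0.37). DEAD-box helicases (Ddx, 9 of 32 higher and 2 lower, 0.33) were higher. So were genes with the stem Eif, many of them translation initiation factors (11 of 54 higher and 1 lower, 0.22). Cytosolic ribosomal proteins passed as sets while few members did: 4 of 45 Rps genes were higher and 1 lower (0.23), and 1 of 62 Rpl genes was higher and 2 lower (0.25). Each family kept its direction under the 4 scalings.

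A group of 20 genes was at the floor in the 3 Acss2-KO libraries and at 4 CPM or more in the 3 WT libraries, 6 of them within the test. Besides Mup19 and Cyp2b9 they included Clec2h (9.06, 7.62 and 10.3 CPM in WT), Sult1c2 (7.62, 6.73 and 6.54 CPM), Zfp60 (7.78, 7.06 and 8.28 CPM) and Zfp874b (8, 6.45 and 7.67 CPM). Going the other way, Moxd1 was at the floor in WT and at 6.41, 21.6 and 7.73 CPM in Acss2-KO, and Bmper at 32.7, 4.29 and 20 CPM.

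Changes of zinc finger genes (symbols beginning Zfp) differed between chromosome locations in these libraries. In bins of 10 Mb with at least 8 such genes, without a filter on low values, the median log2 fold change was -1 on chromosome 13 (60 to 70 Mb, 13 of 16 genes with every Acss2-KO library below every WT library) and -0.84 on chromosome 7 (20 to 30 Mb, 19 of 23 below and 2 above), but 0.67 on chromosome 6 (40 to 50 Mb, 5 of 9 above and 2 below). These 3 medians kept their signs under the 4 scalings. In the main test, with its minimum of 5 CPM, were only 4 of the 16 genes on chromosome 13. The same held for 7 of the 23 on chromosome 7 and 7 of the 9 on chromosome 6. Most values of the first 2 bins therefore come from low genes. Among all tested genes, 52.9% had no overlap between the groups in either direction. As a family, the 149 Zfp genes in the main test did not pass camera (32 higher and 39 lower, median log2 fold change -0.05). Other bins were mixed, such as that on chromosome 9 (20 to 30 Mb, 4 of 8 below and 3 above, median -0.23). Shuffling the 106 genes 10000 times within strata of WT level gave as wide a spread of the 8 medians with permutation p = 8e-04. The bins were chosen from these same values, and the shuffles treat neighbouring genes as independent. This p therefore measures the spread between genes and cannot decide whether such genes change alike wherever they lie. A change over the whole stretch is argued against for the chromosome 13 bin, whose other genes lay at -0.15 relative to other genes everywhere. Of the 101 genes with a transcript, 3 (3.0%) share over 50% of their 36-base words with another gene. This argues against reads shared between near-identical coding copies for most of these genes. It cannot decide the matter for other copies, since only coding transcripts were compared and the counting of multiply matching reads is not given. Zfp65, Zfp729a and Zfp729b of the chromosome 13 bin had no transcript to compare. A difference in genetic background between the 2 mouse stocks may remain beside an effect of genotype, and neither was tested, since the labels give the same strain for both.

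The values of 8 genes, Lepr, Cdkn1a, Mt2, Per1, Pdk4, Ddit4, Zbtb16 and Tat, led to the hypothesis that glucocorticoid-induced genes were higher in Acss2-KO livers. A list of textbook glucocorticoid targets was then written without those 8, and 6 more whose values had been seen were left out of the test. Of the 11 others tested, 5 were higher and none lower (median log2 fold change 1.12, camera p = 0.0012, and p = 0.062 with an estimated correlation), such as Fkbp5 (45.3, 56.1 and 69.6 CPM in WT, and 180, 207 and 169 CPM in Acss2-KO) and Gadd45b (4.72-fold higher). Tsc22d3 and Klf15, from the same list, did not pass (adjusted p = 0.25 and 0.17). The test used the same 6 libraries that led to the hypothesis, so it is no independent evidence for more glucocorticoid signalling. Several of these genes also answer to other stress pathways, and no hormone was measured.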
